A study of Homo sapiens with 24 samples.

How the data were processed

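RNA was measured from LNCaP cells, a human prostate cancer line, after nucleofection with 2.5 µg of plasmid for miR-130a, miR-203, miR-205 or a scramble control, per the labels' protocols. Each transfection gave total RNA and RNA bound to AGO2, taken by co-immunoprecipitation, with 3 arrays labelled as biological replicates for each of the 8 groups. The arrays were Affymetrix oligonucleotide arrays for human genes and received 2 µg of RNA each, per the labels.

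The deposited values are log2 expression per probe set, already background-corrected and summarized by the authors. The submitters' processing notes name R 2.9.0, GCRMA and RMA, with no version for GCRMA or RMA and no order of use. The values held 22277 probe sets on 24 arrays, between 2.34 and 14.5 on the log2 scale. On each array 27.3% to 30.3% of probe sets lay exactly at the lowest value and 39.9% to 41.5% within 0.05 of it, so changes of dim transcripts are compressed. The lowest value took 3 levels, shared by the 6 arrays of miR-130a, the 6 arrays of miR-203 and the 12 arrays of miR-205 and scramble. The arrays thus appear to have been normalized in 3 separate runs, which moves any difference between runs into the comparisons of miR-130a and miR-203 with scramble. No step of the original processing was repeated. For arrays no depth per sample applies, and the number of arrays limits the precision.

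Probe sets were named through the platform annotation: 19064 had 1 gene symbol, 1043 had several, 2108 were unnamed here and 62 were controls. Of those with 1 symbol, 19052 were matched to a reference gene table through their gene ID, and 0 symbols changed. These gave 11963 genes, each measured by its probe set with the highest mean over all arrays; 4310 genes had several probe sets. Genes whose probe set had a mean under the median of all probe sets (2.85) were left out, which left 6782. Of the genes the naming rule lists, ZEB1 lay below this filter and the AGO2 gene is not analysed here; another is not reported here. A group whose 3 arrays all lay within 0.05 of the floor has no measured level, and a change against it is given as a lower bound.

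Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a Benjamini-Hochberg adjusted p under 0.05. The 12 arrays of AGO2-bound RNA and the 12 arrays of total RNA were fitted apart for the comparisons of each microRNA with scramble. All 24 arrays entered the fit for AGO2-bound against total RNA and for the difference between the AGO2 change and the total RNA change. Gene lists, 35 of them, were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives named as planned. The 30 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation keeps 3 of the 43 list calls of the 10 comparisons: the interferon list in total RNA after miR-130a and after miR-203, and the heat shock and unfolded protein response list in total RNA after miR-203. The other list calls rest on the preset.

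Named genes were the 10 largest rises and falls past the threshold whose groups did not overlap (5 each way for the difference of changes), the list members with the smallest p, the known targets past the threshold, KLK3 and ERBB3, genes raised in AGO2-bound and lowered in total RNA, and the 10 genes raised by all 3 microRNAs with the largest smallest rise. The same rule was applied to shared falls after their values were seen. Overlaps were set beside independent lists and beside 100 simulations of unchanged groups against the same scramble arrays.

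The labels give each group the replicate numbers 1 to 3. Deviations of arrays with the same number from their group means correlated at 0.11 to 0.52 for AGO2-bound RNA of miR-130a and scramble and at 0.16 to 0.58 for miR-203 and scramble, so the numbers pair these arrays, as a property of the data and not of a stated design. The mean of spiked control probe sets also rose from number 1 to 3 in every AGO2-bound group. It rose from 6.57 to 8.35 after miR-205 and from 7.08 to 7.93 after scramble (log2). The number thus marks AGO2-bound arrays of miR-205 too, and the main tests did not include it. The labels call the arrays biological replicates without naming separate cultures, and the p-values measure the spread between these arrays.

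Alternatives changed the filter, the probe set per gene, the scaling between arrays, the spread prior, array weights, the threshold, the arrays in the fit, the replicate number as a block and each array in turn. The test was also tested on simulated data with 200 changed genes among 6782. It recovered 29.9%, 91.0% and 100% of genes changed 1.5-, 2- and 4-fold for AGO2-bound RNA after miR-205, with 13 false calls. For total RNA after miR-205 it recovered 86.6%, 98.5% and 100%, with 22 false calls. For the difference of changes after miR-205 it recovered 25.4%, 68.7% and 100%, with 6 false calls, and for AGO2-bound against total scramble RNA 53.7%, 97.0% and 100%, with 9. Genes of a further simulated list, raised 2-fold, were left out of these counts. The simulated noise was independent between genes and arrays, without pairing or run offsets, and fewer genes changed than in the data. These figures therefore do not give the error rates of the real comparisons. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.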

Results

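LNCaP is a human prostate cancer cell line that responds to androgen. The series asked which transcripts miR-130a, miR-203 and miR-205 bind directly in these cells. Each microRNA, or a scramble control, was supplied from 2.5 µg of plasmid by nucleofection, a form of electroporation. RNA was then taken either from the whole cell (total RNA) or from an immunoprecipitate of AGO2, the Argonaute protein that holds microRNAs and the transcripts they pair with. Each of the 8 combinations of 4 transfections and 2 kinds of RNA was measured in 3 biological replicates, on 24 oligonucleotide arrays that received 2 µg of RNA each. Every array carried 22277 probe sets, and between 39.9% and 41.5% of them lay at the floor of the log2 scale. After the filter on signal, 6782 genes were compared. The number of arrays, 3 per group, limits the precision.

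The lowest log2 value was the same on all arrays within each of 3 sets. It was 2.344895 on the 6 arrays of miR-130a, 2.346843 on the 6 arrays of miR-203 and 2.347327 on the 12 arrays of miR-205 and scramble. The values therefore appear to come from 3 normalization runs, with miR-205 in the run of the control and miR-130a and miR-203 each in another. For both of these, run and transfection coincide, so an offset between runs can be part of each level and change against scramble given below. In total RNA, 42 spiked control probe sets above the floor differed from scramble by a median of 0.25 after miR-130a, 0.15 after miR-203 and 0.092 after miR-205 in either direction (log2). This difference was not computed for AGO2-bound RNA. There the SD of the mean spiked signal within a group was 0.33 to 0.91, against 0.04 to 0.09 in total RNA. The small differences in total RNA therefore do not speak for the AGO2 comparisons. The excess of the AGO2 change over the total RNA change removes an offset that is equal in both kinds of RNA of a run, and AGO2-bound against total RNA within a transfection never crossed runs.

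Changes are given as log2 differences ± SE from limma, between 3 arrays and 3 arrays unless stated, and adjusted p is the Benjamini-Hochberg value over the 6782 genes. For gene lists fixed beforehand, counts of members adjusted over the list alone are named where they differ from the counts over all genes. AGO2-bound RNA differed from scramble at 2609 genes after miR-130a, 3487 after miR-203 and 2986 after miR-205. Total RNA differed at 1984, 2687 and 1591 genes. Of the total scramble arrays used in these comparisons, replicate 1 stood apart on control probe sets. Its 18S ribosomal RNA signal was 4.33, against 2.83 and 3.05 on replicates 2 and 3, its 3 prime over 5 prime difference of GAPDH 0.99 against 0.68 and 0.64, and that of ACTB 2.44 against 2.12 and 2.10 (log2). Without this array total RNA differed at 1900, 2522 and 1483 genes. Changes of at least 2-fold were found at 910, 1319 and 1150 genes in AGO2-bound RNA and at 156, 256 and 186 genes in total RNA.

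**Figure D1:**
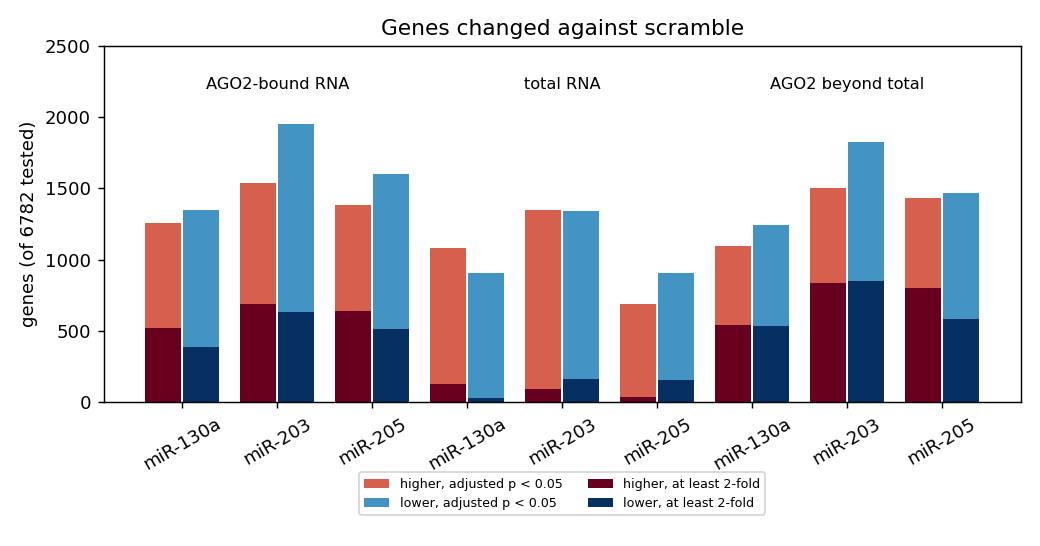
Number of genes (y axis, of 6782 tested) higher or lower than scramble after each microRNA (x axis), in AGO2-bound RNA, in total RNA and for the AGO2 change beyond the total RNA change. Light bars count all genes with an adjusted p under 0.05 and dark bars those changed at least 2-fold; the dark bars in AGO2-bound RNA stand for 910, 1319 and 1150 genes and those in total RNA for 156, 256 and 186.

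Total RNA after miR-205 was marked by lower levels of cell cycle genes. Of 42 cell cycle and proliferation genes tested, 39 fell and 1 rose, with a median change of -1.21. AURKB, a mitotic kinase, fell by 1.44 ± 0.11 (adjusted p = 5.1e-06), UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, by 1.40 ± 0.13, and MCM5 and MCM7, subunits of the replicative helicase, by 1.78 ± 0.17 and 1.35 ± 0.13. The mitotic genes DLGAP5 (-1.91 ± 0.34), TPX2 (-1.86 ± 0.26) and CDC20 (-1.81 ± 0.23) were among the 10 largest falls. The list was lower than other genes by camera (adjusted p = 1.4e-21; adjusted p = 0.11 with an estimated correlation), and adjusted over the list alone 39 members were again lower and 1 higher.

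Androgen-responsive genes rose in the same samples, with 11 of 25 higher and 2 lower, the same counts adjusted over the list alone. FKBP5, an immunophilin, rose by 1.92 ± 0.11 (adjusted p = 7.0e-07), MAF by 1.88 ± 0.14 and ELL2, an elongation factor, by 1.38 ± 0.20. KLK3, which encodes prostate-specific antigen, rose by 0.50 ± 0.10 (adjusted p = 0.0041). Cholesterol and fatty acid synthesis genes rose at 13 of 22 members and fell at 1, among them MSMO1 (0.98 ± 0.09), LSS (0.80 ± 0.09) and HMGCS1 (0.77 ± 0.11). By camera the adjusted p was 0.00041 for the androgen-responsive list and 8.3e-05 for the cholesterol list, and with an estimated correlation the adjusted p was 0.11 for both. Without total scramble replicate 3, 8 members of the cholesterol list rose, and the androgen-responsive median of 0.24 was 0.15 without total miR-205 replicate 3. Further large rises were ANKRD46 (2.13 ± 0.13), SEMA6A (1.73 ± 0.17), GHR, the growth hormone receptor (1.69 ± 0.15) and CDC42EP3 (1.64 ± 0.10).

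Of 26 heat shock and unfolded protein response genes, 10 fell in total RNA after miR-205 and none rose. The members with the smallest p were ASNS (-1.62 ± 0.11), DDIT3 (-1.54 ± 0.14), TRIB3 (-1.28 ± 0.13), ATF4 (-0.86 ± 0.09) and CHAC1 (-1.86 ± 0.23). These are not heat shock proteins and are known from the response to amino acid shortage as well as the unfolded protein response. No value here tells these responses apart. This list had an adjusted p of 0.0057 by camera, and the adjusted p was 0.11 with an estimated correlation. PCK2, a mitochondrial enzyme of gluconeogenesis, fell by 1.94 ± 0.10 and HMOX1, heme oxygenase, by 2.08 ± 0.28. Mitochondrial ribosomal protein genes fell at 11 of 46 members, with MRPL23 at -0.64 ± 0.09, and proteasome genes at 4 of 27, 3 adjusted over the list alone, with PSMD8 at -0.57 ± 0.09. Their adjusted p by camera was 0.012 and 0.030, and the adjusted p was 0.54 and 0.78 with an estimated correlation. Without total miR-205 replicate 3 both calls ended, with 4 and 2 members lower (camera adjusted p = 0.051 and 0.12). Without total miR-205 replicate 1, 7 and 2 were lower, and the proteasome call also ended without total scramble replicate 1 (camera adjusted p = 0.062). TGF-beta and BMP pathway genes rose at 2 of 23, ID2 (0.91 ± 0.24) and SMURF2 (0.42 ± 0.14), and at 1 adjusted over the list alone, with an adjusted p of 0.030 by camera and an adjusted p of 0.56 with an estimated correlation. That list call ended without total miR-205 replicate 1 or 3 or total scramble replicate 2 (camera adjusted p = 0.10, 0.098 and 0.11), and from 0 to 4 members rose when 1 array was left out. The ID2 call ended without total miR-205 replicate 1 (0.69, adjusted p = 0.067) and without total scramble replicate 2 (0.83, adjusted p = 0.054), and the SMURF2 call without total miR-205 replicate 1 or 3 or total scramble replicate 2 or 3 (0.29 to 0.44, adjusted p = 0.082 to 0.17). The interferon list had a median of 0.02. In all, 686 genes rose and 905 fell by limma; 980 genes changed when all 24 arrays entered the fit, and 640 changed by at least 1.5-fold.

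AGO2-bound RNA after miR-205 gained transcripts of KRAB zinc finger genes, a large family of DNA-binding repressors. Of 44 tested, 32 rose and 2 fell, with a median change of 1.27 and the same counts adjusted over the list alone. ZNF184 rose by 4.34 ± 0.17 (adjusted p = 4.6e-10), ZNF354A by 4.0 ± 0.16, ZNF195 by 3.70 ± 0.16 and ZNF180 by 3.30 ± 0.14. The 10 largest rises also held ZNF79 (4.24 ± 0.17), ZNF551 (4.19 ± 0.13), ZNF571 (4.07 ± 0.18), ZNF83 (3.96 ± 0.19) and ZNF606 (3.96 ± 0.21). The largest rise was RPA3, a subunit of the single-strand DNA-binding complex of replication, at 5.93 ± 0.22 (adjusted p = 3.5e-10), followed by VPS16 (4.70 ± 0.15) and SCAND1 (4.53 ± 0.21). The KRAB list was higher than other genes by camera (adjusted p = 7.9e-13; adjusted p = 0.67 with an estimated correlation). In total RNA the median change of the same list was 0.05.

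**Figure D2:**
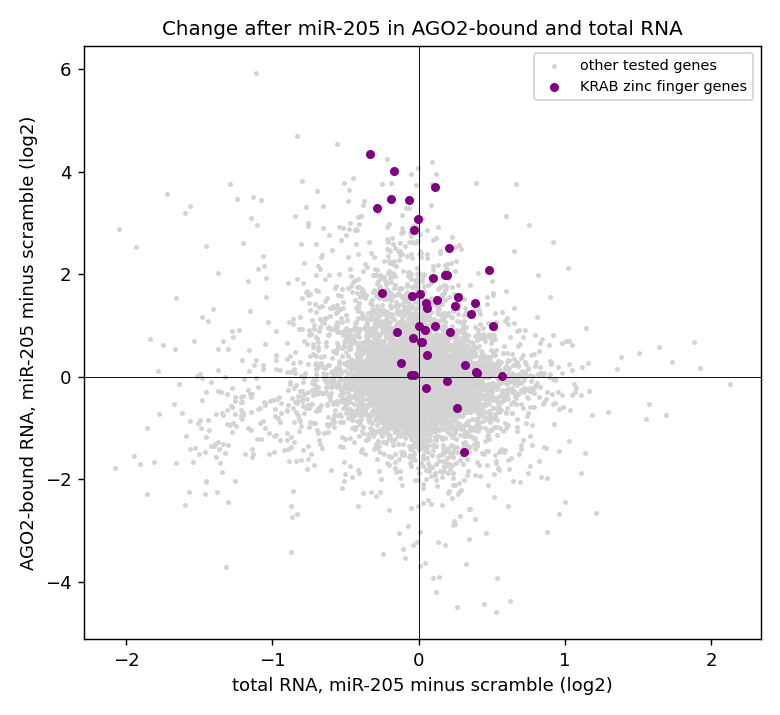
Change after miR-205 against scramble (log2, means of 3 arrays each) in total RNA (x axis) and in AGO2-bound RNA (y axis), with each of the 6782 tested genes as a point. The 44 KRAB zinc finger genes (purple) lie around a median of 1.27 on the y axis and 0.05 on the x axis.

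The largest falls in AGO2-bound RNA after miR-205 were TRIP4 (-4.60 ± 0.16), STAM (-4.50 ± 0.15), CCNG1, or cyclin G1 (-4.44 ± 0.17), the interferon-inducible IFI6 (-4.37 ± 0.52), COPS3 (-4.20 ± 0.18) and TMEM126B (-3.93 ± 0.19). Cell cycle genes fell at 18 of 42 members and none rose, with KIF20A at -3.71 ± 0.27, CDK2 at -1.62 ± 0.22 and CCNB2 at -2.51 ± 0.38. Their list was called by camera (adjusted p = 0.0049), with an adjusted p of 0.93 with an estimated correlation. The list medians of the 3 miR-205 arrays over the scramble mean were -0.17, -0.93 and -0.95, and those of the scramble arrays 0.37, 0.017 and -0.37, so miR-205 replicate 1 lay above a scramble array. Replicate 1 had the highest list median in every group of AGO2-bound RNA. Each miR-205 array lay below the scramble array of its own number. Without AGO2 miR-205 replicate 1, 25 members fell (camera adjusted p = 0.00011), and without AGO2 scramble replicate 1 the call ended, with 14 lower (camera adjusted p = 0.071). Altogether 1382 genes rose and 1604 fell.

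Beyond the change in total RNA, 1430 genes rose in AGO2-bound RNA after miR-205 and 1470 fell, in a test of the difference between both changes. The largest excesses were RPA3 (7.03 ± 0.26), VPS16 (5.53 ± 0.21), the mitochondrial citrate carrier SLC25A1 (5.28 ± 0.29), SCAND1 (5.09 ± 0.25) and MLST8, an mTOR complex subunit (5.05 ± 0.21). TRIP4 (-5.12 ± 0.25), IFI6 (-4.99 ± 0.56), CCNG1 (-4.88 ± 0.19), STAM (-4.76 ± 0.20) and SNX7 (-4.47 ± 0.26) had the largest deficits. The KRAB list rose at 31 of 44 members and fell at 2, or 31 and 3 adjusted over the list alone, with a median of 1.03 (camera adjusted p = 4.4e-09; adjusted p = 0.50 with an estimated correlation).

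Interferon response genes rose in total RNA after miR-130a, set against scramble across normalization runs. Of 29 interferon response genes tested, 28 rose and none fell, over all genes and adjusted over the list alone, and the median change was 3.01. The chemokine gene CXCL10 rose by 7.85 ± 0.09 (adjusted p = 5.0e-15), and the antiviral genes IFIT2 by 7.17 ± 0.11, IFIT1 by 6.93 ± 0.09, OASL by 6.77 ± 0.14, IFIT3 by 6.76 ± 0.13 and RSAD2 by 6.05 ± 0.12. RIGI, a sensor of viral RNA, rose by 5.64 ± 0.15 and HERC5 by 5.28 ± 0.14. The chemokine genes CCL5 and CXCL11 were at the floor on all 3 scramble arrays, so their rises of 6.92 ± 0.09 and 6.74 ± 0.15 are lower bounds. The list was called by camera with the preset correlation (adjusted p = 2.1e-40) and with an estimated correlation (adjusted p = 0.0054).

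Cell cycle genes rose at 17 of 42 members in total RNA after miR-130a, 22 adjusted over the list alone, and none fell. CDC25A, a phosphatase that activates cyclin-dependent kinases, rose by 1.33 ± 0.11, BUB1B by 1.00 ± 0.18 and CDK1 by 0.80 ± 0.14. Cholesterol and fatty acid synthesis genes rose at 10 of 22 members, 11 adjusted over the list alone, with MSMO1 at 1.39 ± 0.09 and HMGCS1 at 1.30 ± 0.11. Androgen-responsive genes rose at 8 of 25, or 9 with 3 lower adjusted over the list alone, with FKBP5 at 1.75 ± 0.11 and HPGD at 1.12 ± 0.10, while KLK3 was at -0.29 ± 0.10 (adjusted p = 0.052). Immediate early genes rose at 7 of 17, 8 adjusted over the list alone, led by KLF4 (3.45 ± 0.12), CCN1 (1.14 ± 0.13) and JUN (0.78 ± 0.15). Oxidative phosphorylation genes fell at 9 of 55 and rose at 1, or 5 and 0 adjusted over the list alone, with COX7B at -0.52 ± 0.08. Camera's adjusted p was 7.0e-06 for cell cycle, 0.00037 for cholesterol, 0.026 for androgen-responsive, 0.0049 for immediate early and 0.0077 for oxidative phosphorylation genes. With an estimated correlation the adjusted p was 0.38, 0.20, 0.28, 0.20 and 0.34 for these lists. The androgen-responsive call ended without total scramble replicate 1 (camera adjusted p = 0.052). Without total miR-130a replicate 1 or total scramble replicate 3, 11 cell cycle genes rose and 5 oxidative phosphorylation genes fell, and without total miR-130a replicate 3, 4 immediate early genes rose and 5 oxidative phosphorylation genes fell.

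The largest falls in total RNA after miR-130a were HMOX1 (-2.13 ± 0.28), CHAC1 (-1.82 ± 0.23), the cystine transporter SLC7A11 (-1.57 ± 0.13), PCK2 (-1.55 ± 0.10), ASNS, asparagine synthetase (-1.51 ± 0.11), DDIT3 (-1.50 ± 0.14), FAHD2A (-1.48 ± 0.11) and GPNMB (-1.34 ± 0.10). Across the normalization runs 1081 genes rose and 903 fell, or 54.5% of calls higher; the share was 44.2% with quantile normalization within each kind of RNA and 43.7% with each array centred on its median. With all 24 arrays in the fit 1202 genes changed, and 693 changed by at least 1.5-fold.

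**Figure D3:**
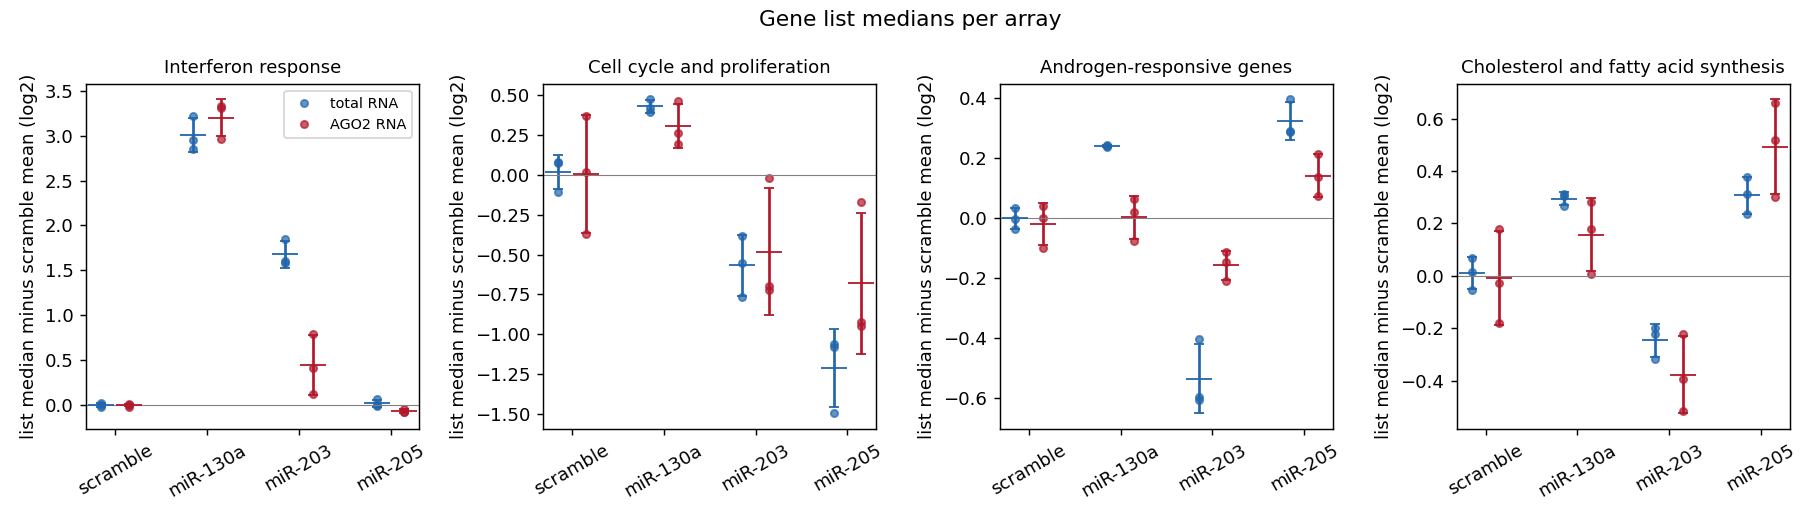
Median over the members of 4 gene lists on each array minus the scramble mean (y axis, log2), by transfection (x axis), for total (blue) and AGO2-bound RNA (red); points are the 3 arrays of a group, and bars their mean and SD. The interferon list lies at 3.01 ± 0.19 in total RNA after miR-130a, 1.68 ± 0.15 after miR-203 and 0.02 ± 0.04 after miR-205, and miR-130a and miR-203 were normalized apart from scramble.

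In AGO2-bound RNA after miR-130a the interferon list rose at 25 of 29 members, with a median of 3.09, again across runs. IFIT1 rose by 6.93 ± 0.31, CCL5 by 5.99 ± 0.41, OASL by 5.97 ± 0.30, IFIT2 by 5.75 ± 0.23 and CXCL10 by 5.42 ± 0.24. IFNB1, the interferon beta gene itself, was at the floor in scramble and higher by at least 5.03 ± 0.15 (adjusted p = 6.1e-11), and DHX58 by at least 4.50 ± 0.17. The list had an adjusted p of 5.4e-21 by camera, and the adjusted p was 0.19 with an estimated correlation. STAM (-5.76 ± 0.15), SMIM7 (-4.58 ± 0.19), the chaperone gene PFDN2 (-4.32 ± 0.19), WASHC5 (-4.16 ± 0.18) and CCNG1 (-4.15 ± 0.17) had the largest falls. The ACTB probe sets of the 3 prime end exceeded those of the 5 prime end by 2.55 ± 0.30 (SD, n = 3) on these arrays and by 3.40 ± 0.45 in AGO2-bound scramble RNA. In all 1259 genes rose and 1350 fell.

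The change beyond total RNA after miR-130a left 1096 genes higher and 1245 lower. The interferon list was not called in this test, and mitochondrial ribosomal protein genes rose at 18 of 46 members and fell at 5, or 18 and 6 adjusted over the list alone, with MRPS35 at 3.30 ± 0.20 and MRPL28 at 2.69 ± 0.27 (camera adjusted p = 0.021; adjusted p = 0.79 with an estimated correlation). That call ended without AGO2 miR-130a replicate 1, where the list median fell from 0.37 to 0.24 (camera adjusted p = 0.062). ACAA1, a thiolase of peroxisomal fatty acid oxidation (5.07 ± 0.21), NUDT9 (5.04 ± 0.20), PRPSAP2 (4.60 ± 0.24), RNF7 (4.57 ± 0.21) and GCLM, a subunit of the enzyme that starts glutathione synthesis (3.97 ± 0.23), rose most. STAM (-6.04 ± 0.20), DPM2 (-4.74 ± 0.21) and CCNG1 (-4.45 ± 0.19) fell most.

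Interferon response genes also rose in total RNA after miR-203, across the runs, with 23 of 29 members higher (24 adjusted over the list alone), none lower and a median of 1.72. IFIT1 rose by 5.17 ± 0.09 (adjusted p = 2.4e-12), OASL by 5.10 ± 0.14, IFIT2 by 4.93 ± 0.11, CXCL10 by 4.48 ± 0.09 and RSAD2 by 3.55 ± 0.12. The list was called by camera with the preset (adjusted p = 2.5e-17) and with an estimated correlation (adjusted p = 0.041). Set directly against miR-130a total RNA, which came from another run, the list was higher after miR-130a by a median of 1.44, with 28 of 29 members higher and 29 adjusted over the list alone (camera adjusted p = 6.7e-18; adjusted p = 0.038 with an estimated correlation).

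Androgen-responsive genes fell in total RNA after miR-203, with 15 of 25 lower and 2 higher over all genes and adjusted over the list alone. The membrane protease gene TMPRSS2 fell by 1.55 ± 0.12 (adjusted p = 1.5e-06), KLK2 by 1.54 ± 0.12, KLK3 by 1.22 ± 0.10 and ABCC4 by 1.35 ± 0.12. Cell cycle genes fell at 28 of 42 members and rose at 2, or 32 and 2 adjusted over the list alone, with RRM2, a ribonucleotide reductase subunit, at -1.41 ± 0.16 and BUB1 at -1.10 ± 0.17. Cholesterol and fatty acid synthesis genes fell at 9 of 22, or 10 with 1 higher adjusted over the list alone, with FADS2 at -1.26 ± 0.15 and SQLE at -0.92 ± 0.14. Camera's adjusted p was 8.2e-05, 5.2e-07 and 0.028 for these lists, and the adjusted p was 0.079, 0.37 and 0.37 with an estimated correlation. The cholesterol call ended without total scramble replicate 2 (camera adjusted p = 0.051). The heat shock and unfolded protein response list fell at 16 of 26 members, 18 adjusted over the list alone, again with ASNS (-1.13 ± 0.11), TRIB3 (-1.35 ± 0.13) and ATF4 (-0.97 ± 0.09) in front, by camera with the preset (adjusted p = 6.3e-06) and with an estimated correlation (adjusted p = 0.035).

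Histone genes rose at 7 of 11 members and fell at 1 in total RNA after miR-203, led by H2BC21 (1.84 ± 0.10) and H2BC5 (1.02 ± 0.12). TGF-beta and BMP pathway genes rose at 7 of 23, with BAMBI, a pseudoreceptor of the pathway, at 1.88 ± 0.11, and immediate early genes at 8 of 17, with DUSP2 at 1.90 ± 0.14. These lists had an adjusted p of 0.0027, 0.034 and 0.039 by camera, and the adjusted p was 0.16, 0.37 and 0.24 with an estimated correlation. The TGF-beta and immediate early calls ended without total miR-203 replicate 1 (camera adjusted p = 0.052 and 0.059) and without total scramble replicate 2 (camera adjusted p = 0.069 and 0.061). The largest falls were COX6A1, a cytochrome c oxidase subunit (-2.40 ± 0.15), LASP1, an actin-binding protein (-2.19 ± 0.11, adjusted p = 3.2e-08), KIF5C (-2.12 ± 0.14), CPT1A, which controls mitochondrial fatty acid uptake (-2.12 ± 0.13), and CREBL2 (-2.08 ± 0.12). Across runs 1345 genes rose and 1342 fell, and 1072 changed by at least 1.5-fold.

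AGO2-bound RNA after miR-203 gained most in GTF2H5, a TFIIH subunit (5.01 ± 0.21), ETHE1 (4.91 ± 0.21), PEX16 (4.49 ± 0.19), the E2F partner TFDP2 (4.41 ± 0.21) and NDUFV1, a complex I subunit (4.38 ± 0.25), across runs. It lost PFDN2 (-4.62 ± 0.19), CCNG1 (-4.30 ± 0.17), ANXA4 (-4.03 ± 0.16), SMIM7 (-3.95 ± 0.19) and the ribosomal protein gene RPL11 (-3.93 ± 0.19). Of 22 known let-7 targets, 15 fell and 1 rose, or 16 and 1 adjusted over the list alone, with FAS at -1.62 ± 0.17 and CDC34 at -1.02 ± 0.13 (camera adjusted p = 0.037). The interferon list rose at 12 of 29 and fell at 3, with OASL at 3.80 ± 0.30 (camera adjusted p = 0.037). The adjusted p was 0.85 for both lists with an estimated correlation. Both calls ended without AGO2 miR-203 replicate 2 (camera adjusted p = 0.093 for let-7 targets and 0.097 for the interferon list), and that of let-7 targets without AGO2 scramble replicate 2 (camera adjusted p = 0.056). KLK3 fell by 2.02 ± 0.17. The 3 prime over 5 prime difference was 2.68 ± 0.34 (SD, n = 3) for ACTB and 0.77 ± 0.15 for GAPDH on these arrays, against 3.40 ± 0.45 and 1.40 ± 0.17 in AGO2-bound scramble RNA. The 18S ribosomal RNA control probe sets read 8.64 ± 0.50 against 7.63 ± 0.29, and the ranges of the 3 arrays were apart for GAPDH and 18S and nearly touched for ACTB. In all 1537 genes rose and 1950 fell.

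Beyond total RNA, 1500 genes rose and 1829 fell after miR-203. GTF2H5 (5.35 ± 0.24), CHCHD3 (5.23 ± 0.22), ETHE1 (5.07 ± 0.28), NDUFV1 (4.70 ± 0.28) and ARPC1B (4.51 ± 0.22) rose most, and IFI6 (-5.01 ± 0.56), CCNG1 (-4.92 ± 0.19) and PFDN2 (-4.86 ± 0.23) fell most. The interferon list lay below its total RNA change at 18 of 29 members, with a median of -1.12, IFIT2 at -3.42 ± 0.27 and CXCL10 at -3.32 ± 0.27. Proteasome genes rose at 13 of 27 and fell at 5 (14 and 5 adjusted over the list alone), with PSMB6 at 3.67 ± 0.23, and KRAB zinc finger genes fell at 23 of 44 and rose at 3 (23 and 4 adjusted over the list alone), with ZNF586 at -1.65 ± 0.19. Camera's adjusted p was 0.00014, 0.036 and 0.036 for the 3 lists, and the adjusted p was 0.68, 0.75 and 0.75 with an estimated correlation. Both the proteasome and the KRAB call ended without AGO2 miR-203 replicate 2 (camera adjusted p = 0.058) or AGO2 scramble replicate 2 (camera adjusted p = 0.053), and the KRAB call also without AGO2 miR-203 replicate 1 (camera adjusted p = 0.061) or AGO2 scramble replicate 3 (camera adjusted p = 0.055).

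Lists of published targets of the 3 microRNAs were not called by camera in their own microRNA's comparisons, with an adjusted p of 0.82 in AGO2-bound and 0.80 in total RNA for miR-205, 0.80 and 0.62 for miR-203, and 0.45 and 0.79 for miR-130a. Of 19 tested miR-205 targets, 5 rose and 2 fell in AGO2-bound RNA, and 3 rose and 5 fell in total RNA, or 4 and 5 adjusted over the list alone. YY1 rose by 1.62 ± 0.17 and VEGFA, a growth factor of blood vessels, by 1.38 ± 0.15 in AGO2-bound RNA. ERBB3, a receptor tyrosine kinase, was lower by 0.34 ± 0.09 in total RNA after miR-205 (adjusted p = 0.013), a call that ended without total miR-205 replicate 1 (-0.30, adjusted p = 0.058) and with all 24 arrays in the fit (adjusted p = 0.18). In AGO2-bound RNA ERBB3 was at 0.29 ± 0.20 (adjusted p = 0.26). Its AGO2 change beyond total RNA after miR-205 was called higher. This call ended without AGO2 miR-205 replicate 2 or 3, AGO2 scramble replicate 1, total miR-205 replicate 1 or total scramble replicate 2. The excess was then 0.47 to 0.61 (adjusted p = 0.051 to 0.085). After miR-130a, across runs, ERBB3 was called higher in AGO2-bound RNA. That call ended without AGO2 miR-130a replicate 2 or 3 or AGO2 scramble replicate 1 or 2 (0.43 to 0.58). Of 21 miR-203 targets, 3 rose and 3 fell in AGO2-bound RNA across runs. LASP1 rose there by 0.79 ± 0.13, and its AGO2 change exceeded that of total RNA by 2.97 ± 0.17 (adjusted p = 8.1e-13). Of 9 miR-130a targets, 4 rose and 1 fell in AGO2-bound RNA across runs, with SMAD4, a TGF-beta signal transducer, at 1.44 ± 0.17 and DNMT1, a DNA methyltransferase, at 1.08 ± 0.20.

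The 3 microRNAs shared more losses than gains in AGO2-bound RNA. All 3 lowered 472 genes and raised 112, where independent lists would share 91.8 and 58.1. Simulated unchanged groups against a common set of simulated scramble arrays shared 0 on average, a count that holds no real changes and does not measure what the shared arrays add to them. The largest shared falls, chosen by size after the values were seen, were CCNG1, TMEM126B, PFDN2, SNX7, STAM, TSG101, COPS3, WASHC5, COPS5 and SMIM7, and the smallest of these falls was -3.06. COPS3 and COPS5 encode subunits of the COP9 signalosome. The genes raised by all 3 with the largest smallest rise were RPP40, CITED2, ID2, CTSZ, GADD45B, CPSF6, HMOX2, CTSH, TFB2M and NDUFV1. At least 2 microRNAs raised 931 genes. Across genes, which are not independent replicates, the AGO2 changes of pairs of microRNAs correlated at r = 0.33, 0.31 and 0.36, and their covariances of 0.22, 0.21 and 0.27 compare with 0.018 in the simulation, where r was 0.50. The scramble arrays are too few to split, so part of the excess may come from them, and 2 of the 3 comparisons cross runs.

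Some transcripts gained in AGO2-bound RNA while falling in total RNA. For miR-205, within a run, 283 genes did so, against 184 for independent lists, among them TRAM1 (2.53 ± 0.13 and -1.93 ± 0.10), SLC25A1 (3.56 ± 0.25 and -1.72 ± 0.12), HRAS (3.19 ± 0.15 and -1.59 ± 0.11), IFT27 (2.88 ± 0.14 and -2.05 ± 0.15) and CDK2AP2 (3.33 ± 0.16 and -1.57 ± 0.12). For miR-203, across runs, 380 genes did so against 304, with CHCHD3 (3.57 ± 0.18 and -1.66 ± 0.12), SLC50A1 (2.71 ± 0.18 and -1.43 ± 0.09), PEA15 (2.03 ± 0.18 and -1.37 ± 0.09), COX6A1 and CORO1B in front. For miR-130a, across runs, 191 genes did so against 168, with ACAA1 (4.21 ± 0.19 and -0.86 ± 0.09), NUDT9 (4.04 ± 0.18 and -1.01 ± 0.07), CEBPG, MOCOS and TRIB3 in front. Changes with the same sign in both kinds of RNA were in larger excess after miR-130a, with 256 genes raised in both kinds of RNA against 200.7 for independent lists and 220 lowered in both against 179.7. After miR-203, 291 were raised in both against 304.8 and 401 lowered in both against 385.9, and after miR-205, 96 against 139.8 and 230 against 214.0. The mirror pattern, lowered in AGO2-bound and raised in total RNA, was also in excess after miR-205, with 197 genes against 162.2. It held 406 genes against 386.7 after miR-203 and 206 against 215.2 after miR-130a. Over all 6782 genes, the AGO2 and total RNA changes had a Pearson r of -0.082 and a Spearman rho of -0.089 for miR-205, -0.035 and -0.025 for miR-203, and 0.23 and 0.080 for miR-130a. These are correlations across genes, which are not independent replicates, and r for miR-130a was 0.082 without the interferon list.

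AGO2-bound RNA of scramble-transfected cells held a different set of transcripts from total RNA, in a comparison within a run. Of 22 known targets of let-7, a microRNA family, 18 were enriched and 2 depleted, with a median of 2.69, PLAGL2 at 5.27 ± 0.16, E2F6 at 5.03 ± 0.15 and MYC at 4.37 ± 0.15. Immediate early genes were enriched at 16 of 17 members, with DUSP2 at 6.36 ± 0.23, KLF6 at 4.38 ± 0.18 and ZFP36, which speeds decay of AU-rich transcripts, at 4.38 ± 0.20. TGF-beta and BMP pathway genes were enriched at 18 of 23, with TGIF1 at 5.63 ± 0.13 and SMAD7 at 4.96 ± 0.24, and cell cycle inhibitors at 9 of 12, with E2F5 at 4.25 ± 0.14. Apoptosis genes were enriched at 13 of 22, 14 adjusted over the list alone, with BIK at 4.51 ± 0.14, p53 targets at 11 of 17, with TNFRSF10B at 3.53 ± 0.14, RAS-MAPK pathway genes at 18 of 32, with MKNK2 at 3.60 ± 0.12, and mesenchymal genes at 5 of 6, with SNAI2 at 3.94 ± 0.18. Of all 6782 genes, 2378 were enriched and 2565 depleted. Depleted members are counted here for the let-7 list only. The 8 lists had an adjusted p by camera that lay between 5.9e-07 and 0.043, and the adjusted p lay between 0.065 and 0.23 with an estimated correlation. The RAS-MAPK call ended without AGO2 scramble replicate 2 (camera adjusted p = 0.055).

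Transcripts of abundant cellular machines were depleted. Oxidative phosphorylation genes were lower in AGO2-bound RNA at 45 of 55 members and higher at 4, or 46 and 4 adjusted over the list alone, with ATP5F1D at -2.43 ± 0.17 and COX7A2 at -2.30 ± 0.16. Proteasome genes were lower at 24 of 27, with PSMC3 at -2.69 ± 0.16, cytosolic ribosomal protein genes at 33 of 51, with RPS9 at -2.41 ± 0.12, and mitochondrial ribosomal protein genes at 29 of 46, with MRPL48 at -1.99 ± 0.13. RPL11 (2.58 ± 0.15) and RPL35 (2.21 ± 0.14) went the other way, and enriched members of the proteasome and ribosomal lists are not counted here. Camera's adjusted p was 2.7e-07, 5.3e-06, 0.0052 and 0.0048 for the 4 lists, and the adjusted p was 0.23, 0.15, 0.41 and 0.41 with an estimated correlation. ZNF281 (6.86 ± 0.21), PCTP (5.83 ± 0.14) and SERTAD3 (5.74 ± 0.15) were among the most enriched single genes, and EEF1A2 (-5.15 ± 0.16), the glycolytic enzyme gene PKM (-4.82 ± 0.19), EPHX1 (-4.54 ± 0.18) and STIP1 (-4.25 ± 0.18) the most depleted. Control probe sets for 18S ribosomal RNA read 7.63 ± 0.29 (SD, n = 3) in AGO2-bound and 3.40 ± 0.81 in total scramble RNA, and the 3 prime over 5 prime difference of ACTB was 3.40 ± 0.45 and 2.22 ± 0.19. Spiked control probe sets read 7.48 ± 0.43 on AGO2-bound and 6.18 ± 0.05 on total scramble arrays. Enrichment and depletion are therefore relative to the other transcripts on the same arrays. By limma 2378 genes were higher and 2565 lower, and 4858, 4878 and 4928 genes differed between AGO2-bound and total RNA after miR-130a, miR-203 and miR-205, each within its run.

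**Figure D4:**
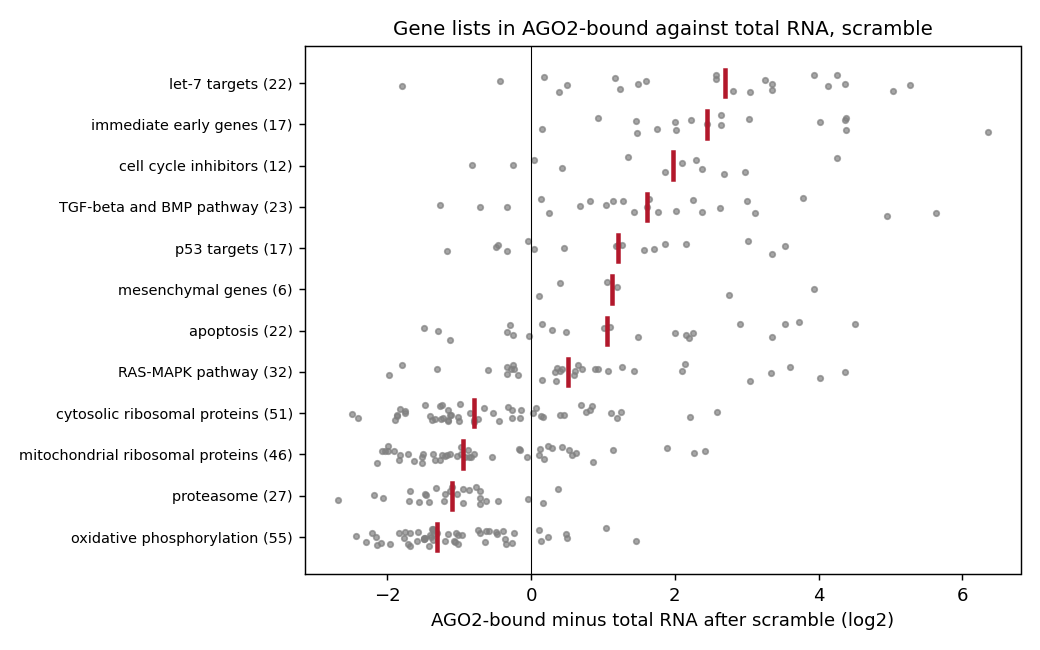
Difference between AGO2-bound and total RNA after scramble (x axis, log2, means of 3 arrays each) for each member (grey points) of the 12 lists called by camera (y axis, number of members in parentheses); red bars mark list medians. Medians run from -1.31 for oxidative phosphorylation to 2.69 for let-7 targets.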

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

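Some tests were chosen after the result was seen. For the interferon genes these were the tests of the run offset and of a response alike to each microRNA plasmid. For the zinc finger pattern they were the tests of the total RNA level and of other zinc finger genes. For the shared falls it was the test of the noise of the scramble arrays.

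Some gene lists were called by camera in opposite directions in total RNA after different microRNAs. The difference itself was also called with the preset correlation (adjusted p at most 6.9e-07), but not always with an estimated correlation. Each difference crosses normalization runs, and an offset between runs can be part of it. Androgen-responsive genes were higher after miR-130a than after miR-203 by a median of 0.85, with 18 of 25 higher and 1 lower (adjusted p = 0.038 with an estimated correlation). The difference of miR-203 from miR-205 for this list was -0.96, with 18 of 25 lower and 2 higher (adjusted p = 0.032 with an estimated correlation). For cell cycle genes, miR-130a exceeded miR-203 by 1.09 and miR-205 by 1.72, with 37 and 40 of 42 members higher (adjusted p = 0.18 and adjusted p = 0.15 with an estimated correlation). For cholesterol and fatty acid synthesis genes, miR-130a exceeded miR-203 by 0.45, with 17 of 22 higher (adjusted p = 0.059 with an estimated correlation). The difference of miR-203 from miR-205 was -0.60, with 17 of 22 lower and 1 higher (adjusted p = 0.035 with an estimated correlation).

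Control probe sets for 18S ribosomal RNA, which no comparison used, were brighter in AGO2-bound than in total RNA by 4.43 after miR-130a, 4.90 after miR-203, 4.09 after miR-205 and 4.23 after scramble (log2).

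Interferon response genes rose in total RNA after miR-130a and miR-203. An offset between runs is argued against: spiked control probe sets, 42 above the floor, differed between miR-130a and scramble by a median of 0.25 in either direction, against a list median of 3.01. A single array is argued against, since the lowest list median among the 6 arrays was 1.58 above the scramble mean. A response alike to each microRNA plasmid is argued against by the miR-205 median of 0.025. A response that the scramble plasmid gives too would cancel in each comparison with scramble, so this median does not test it. A response to these 2 microRNAs and a difference between plasmid preparations or transfections both stay open, and no value here separates them.

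KRAB zinc finger genes rose in AGO2-bound RNA after miR-205 by a median of 1.27. A higher level in the cells is argued against by a total RNA median of 0.054, and probe sets shared between paralogs by a median of 1.11 over the 28 members on gene-specific probe sets (1.40 over the 16 on shared ones). Low signal is argued against, since the list median lay at percentile 100 of 10000 lists matched on signal, whose highest median was 0.38. A rise confined to the listed genes is argued against too: 105 other genes with ZNF symbols had a median of 0.29, at percentile 100 of their own matched lists (highest median 0.14), and 41 of them (39.0%) rose, against 20.4% of all genes. Binding of these transcripts by miR-205 may explain the rise, as a hypothesis found and tested on the same data; sites for miR-205 in the transcripts were not analysed here.

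In AGO2-bound RNA 472 genes were lowered after all 3 microRNAs. In scramble, 382 of them were higher in AGO2-bound than in total RNA, with a median of 1.43, against 2378 of all 6782 genes. The falls are set against the same AGO2-bound scramble arrays, so their selection favours genes that are high there. Independent noise of the scramble arrays is argued against as the whole source of shared changes. Across all tested genes, simulated noise of the fitted spread added a covariance of at most 0.088 times the observed one. How many of the 472 it adds stays open. The simulation holds no shift common to the 3 real scramble arrays and no effect of the replicate number, so it tests neither. A lower level in the cells is argued against: the largest ratio of the median total RNA change to the median AGO2 change was -0.082, with total RNA medians of 0.11, 0.090 and 0.097. Transcripts brought to AGO2 by the scramble transfection and displacement of transcripts from AGO2 by any added microRNA both stay open, since either would give these falls and no value here separates them.

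For each comparison of 3 with 3 arrays, 1 of the 10 splits, the real one, gave as many genes, so the share cannot fall under 0.05. The real values were 2609, 3487 and 2986 genes in AGO2-bound RNA after miR-130a, miR-203 and miR-205, 1984, 2687 and 1591 in total RNA, and 4943 for AGO2-bound against total scramble RNA, and the highest other split gave 0 genes in each by limma. For the paired arrays of AGO2-bound miR-130a and miR-203 against scramble, 4 of the 10 splits part all 3 numbers, and the highest other of these gave 0 genes. Every split but the real one mixes both groups and so moves their difference into the spread. The counts of 0 are therefore no evidence against chance. For the AGO2 change beyond total RNA, 1 of 100 drawn splits of 200 gave as many genes, the real one. Most draws also regrouped the AGO2 arrays and so undid the AGO2 change itself. This share therefore does not test the change beyond total RNA, and chance is not excluded for it. The real values were 2341, 3329 and 2900 and the highest others 2026, 2651 and 2388, all from draws that kept the AGO2 groups; with the AGO2 arrays regrouped the highest were 277, 747 and 394. Of the draws for miR-130a and miR-203, whose AGO2 arrays the numbers pair, 38 and 29 parted all 3 numbers of these arrays, and those of them that regrouped the AGO2 arrays gave at most 118 and 313.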

How the results depend on the processing

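Raising values to the highest run floor, leaving out genes at the floor of a group, leaving out the interferon list and leaving out single arrays for the list calls were chosen after the data were seen; the other alternatives were planned. The counts of changed genes stayed within 1.5 times of the reported ones under most alternatives. With every probe set as a feature they were 3946, 5562 and 4520 in AGO2-bound RNA after miR-130a, miR-203 and miR-205, 3097, 4309 and 2418 in total RNA, 5207 and 4445 for the change beyond total RNA after miR-203 and miR-205, and 8042 for AGO2-bound against total scramble RNA, since more features were tested. With all 24 arrays in the fit, total RNA after miR-130a and miR-205 gave 1202 and 980 genes. The changes stay the same in that fit and only the estimate of their spread differs. The median residual SD was 0.194 there, against 0.147 with the total RNA arrays alone. A minimum of 1.5-fold left 693, 1072 and 640 genes in total RNA, by its construction. Without 1 array at a time the counts ran from 2013 to 2348, 2903 to 3293 and 2349 to 2852 in AGO2-bound RNA, from 1461 to 1900, 2251 to 2522 and 1130 to 1483 in total RNA, from 2017 to 2307, 3062 to 3327 and 2494 to 2955 beyond total RNA, and from 4663 to 4818 for AGO2-bound against total RNA. The 931 genes raised by at least 2 microRNAs became 675 to 830 without a scramble array and 638 to 1227 over all alternatives. Pearson r across genes between AGO2 and total RNA changes ran from 0.216 to 0.240, -0.0471 to -0.0248 and -0.110 to -0.0563 without 1 array, and was 0.0820 and -0.0651 for miR-130a and miR-203 without the interferon list, whose removal is the cause. The share of higher calls moved by over 10 points only in total RNA after miR-130a, from 54.5% to 44.2% with quantile normalization and 43.7% with median centring.

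With the replicate number as a block, the counts were 3318, 4170 and 3611 in AGO2-bound RNA, 1958, 2674 and 1556 in total RNA, 2528, 3466 and 3057 beyond total RNA and 5022 for AGO2-bound against total RNA, and no list call changed. Same-numbered arrays correlated at -0.045 to 0.52 for AGO2-bound miR-205 and scramble RNA, where 2 of 3 correlated best with their own number, and numbers did not pair the total RNA arrays.

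Of 1296 gene results past the threshold among those the naming rule and the lists cover, 78 lost the call without some array and 136 under any alternative. COL6A1, AGO2-bound against total scramble RNA, reversed to -0.096 with the mean of all its probe sets (adjusted p = 0.29); the cause was not tested. Of 43 list calls by camera, 14 ended without some single array. The planned fry test sets a list against no change and not against other genes, so it neither keeps nor loses a camera call; cell cycle genes in AGO2-bound RNA after miR-205 had an adjusted p of 0.066 by it. Signal over background limits dim genes, since 39.9% to 41.5% of probe sets were at the floor. Sets of genes with seed sites for the microRNAs were not run, because no transcript sequences were used here, and a pseudocount did not apply to log2 values.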

Other observations

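The amino acid response list, the 4-fold minimum, the choice of both topics and the tests without the interferon list were made after values were seen; the differences between microRNAs below had not been seen when their tests were written.

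Genes known from the response to amino acid shortage were lower in total RNA after each microRNA. Some of them also belong to the unfolded protein response, and what lowered them was not tested. A list of 30 such genes, 24 of them tested and 4 of these also on the heat shock and unfolded protein response list, fell at 22 members with none higher after miR-205, within a run, with a median of -1.01 (adjusted p = 0.0012 over the 10 comparisons, by camera with an estimated correlation). After miR-130a, across normalization runs, 19 fell and none rose, with a median of -0.76 (adjusted p = 0.0018). After miR-203, also across runs, 20 fell and 1 rose, with a median of -0.64 (adjusted p = 0.0045). The list was written with these falls in view, so its tests are not independent evidence. PCK2 changed by -1.94, -1.80 and -1.55 after miR-205, miR-203 and miR-130a, ASNS, asparagine synthetase, by -1.62, -1.13 and -1.51, and DDIT3, a stress transcription factor, by -1.54, -1.11 and -1.50. All 3 comparisons use the same scramble arrays, so a higher level after scramble would give the same picture. In AGO2-bound RNA the list was not called. There 2 members rose and 9 fell after miR-130a, and 4 rose and 9 fell after miR-203, both across runs. By camera with an estimated correlation the adjusted p was 0.11 and 0.31. In AGO2-bound RNA after miR-205, 7 members rose and 12 fell, with a median of -0.61 (adjusted p = 0.31 by the same test). SHMT2 and PSPH, enzymes of serine metabolism, rose by 1.68 and 1.76 in that comparison with scramble, while CHAC1 and PCK2 fell by 2.28 and 1.55. Beyond total RNA 12 members were higher and 3 lower, with SHMT2 at 2.37 and PSPH at 2.33; CHAC1 was at -0.43 (adjusted p = 0.29) and PCK2 at 0.40 (adjusted p = 0.091).

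Genes raised at least 4-fold in AGO2-bound RNA may fall in total RNA specifically after the microRNA that brought them to AGO2. For miR-205, the median difference of the total RNA change of 181 such genes from the mean of the other 2 microRNAs was -0.19, at percentile 0 of 10000 gene sets matched on signal, whose central 95% ran from -0.075 to 0.037; 63 of the genes fell and 6 rose in their own total RNA, while 40 fell and 18 rose after miR-130a and 33 fell and 29 rose after miR-203. For miR-203, 156 genes gave -0.035, at percentile 2.05, against a lower bound of -0.032; their median total RNA change was -0.15 after miR-203, but also -0.10 after miR-130a and -0.097 after miR-205, where 32 and 23 fell. Without 4 members of the interferon list it was -0.038, at percentile 1.64. For miR-130a, 124 genes gave 0.13, at percentile 99.93, but 18 of them were on the interferon list, which rose in total RNA too; the other 106 gave 0.012, at percentile 55.96, with 29 lowered and 24 raised in total RNA after miR-130a. For miR-205 the values go with the hypothesis but do not single it out. The percentile takes genes as units, and genes are not independent replicates. Genes lowered in AGO2-bound and raised in total RNA were in excess after miR-205 too, with 197 against 162.2 for independent lists. Genes lowered at least 4-fold in AGO2-bound RNA were not tested. A fall specific to the raised genes is thus not told apart from a general inverse relation. For miR-130a no such fall was seen with or without the interferon list, and other induced genes may remain among the 106. For miR-203 the margin is too small to tell a specific fall from a common one. The other 2 microRNAs appear to have been normalized in other runs, so an offset between runs can be part of each difference.

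Probe sets with several gene names or none, 1220 above the filter, changed at 418, 634 and 447 in AGO2-bound RNA after miR-130a, miR-203 and miR-205 and at 310, 463 and 254 in total RNA, the first 2 of each across runs, and 901 differed between AGO2-bound and total scramble RNA by limma.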
